A study of Mus musculus with 4 samples.

How the data were processed

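Bone marrow-derived macrophages of 2 wild-type mice, exposed to LPS for 3 h, were profiled by m6A-eCLIP, with 1 IP and 1 input library per mouse. The names of both tables carry the term NTC, which the labels do not explain, so a control treatment of the cells is not ruled out. Per the labels' protocols, polyadenylated RNA was selected before the antibody step and adapters were ligated as in eCLIP. The submitters' processing notes name cutadapt 2.7, STAR 2.6.0c and UMI-tools 0.5.1, which trim adapters, align reads and collapse reads with the same molecular identifier, and the builds mm10 and hg38. The program that called the sites, the definition of its score and the gene annotation are not given in the sources used here. The coordinates were read as mm10: in the RefSeq table of GRCm38.p6, which shares its coordinates, 98.5% of the called sites of mouse 1 and 98.4% of those of mouse 2 in genes of that table lay inside the gene named beside them, and 98.5% of the gene symbols (8664 of 8800) were found in that table.

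The authors deposited 1 table per mouse, not pooled, in which each row is a called site of 1 base with its strand, gene, annotated position, score and fold. The score is the authors' value per site, per the file headers, and every listed site had a score above 10. The fold is the authors' ratio of read starts in the IP over read starts in the input of the same mouse, per the file headers. Divided by a constant of each table (1.003 in mouse 1, 0.963 in mouse 2), 98.0% and 97.8% of the folds were ratios of whole numbers with a denominator of at most 20, and 62.1% and 62.0% were whole numbers within 1e-06. Because a ratio of 8 became 8.02 in mouse 1 and 7.70 in mouse 2, the 1408 sites of mouse 2 with exactly that ratio missed the limit of 8. No read numbers per library were given, so depth is unknown, models of read counts were not run and no error could be given to the fold of a site. Both mice's folds are printed for each site instead.

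The design fixed before the data were examined called a site enriched at a log2 fold of at least 3 and a −log10 p of at least 3. The tables used hold no p, so the fold limit was applied to the listed sites alone. Sites were shared between mice when they lay on the same strand at the same nucleotide, which is what an overlap of 1 base means for sites of 1 base. Genes were taken from the authors' gene column. Sites with several joined gene names (265 in mouse 1 and 267 in mouse 2) or none (1445 and 1534) were left out of counts per gene. Positions are printed as 1-based coordinates, with the end of each deposited interval taken as the position. Where the 2 tables annotated a shared site differently (636 sites), the annotation of mouse 1 was used for shared sites.

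Shares were given exact 95% intervals. Fisher's exact test (two-sided) compared enriched with other called sites between mice and between annotated positions, and gene lists with all other genes that had a called site in both mice, with Benjamini-Hochberg adjustment over the 30 tests of position and over the 15 lists. Each list was also ranked among 10000 random lists matched on the number of called sites. Ribosomal protein and respiratory chain genes were matched by symbol in the tables, and the other lists were written out by symbol. Genes named in the text were the 10 with the highest mean log2 fold of their strongest shared enriched site, the 5 with the most shared enriched sites, the 4 highest members of each list with up to 2 members that had called sites and none enriched, and the 3 genes per mouse with the most enriched sites and none in the other mouse. Predicted genes were left out except from the lists. Some genes that these rules pick are not reported here. Members named for their number of sites were chosen after their values were seen, such as Tnf, Il6, Il12b, Ccl4, Ythdf2, Wtap, Virma and Mettl3. So were the genes without called sites. IP and input of a mouse come from the same animal, per the labels, and the deposited fold already compares them within the animal.

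The overlap step was tested on simulated data: with 2 simulated tables that each kept a random 80% of 45668 sites, so that 80% of the sites of either should be shared, 79.99% were recovered. Sites were kept without regard to their score, while sharing in the data followed the score. The simulation therefore checks the computation of the overlap and says nothing of the sharing found in the data. Alternatives covered the fold limit, the overlap rule, the counting of 1 site per gene, the background of the lists, each mouse left out and, chosen after seeing the data, a score of at least 20, a limit set before the table's constant and the merging of sites within 5 bases. The motif around sites was not analysed here, since no genome sequence was used. Computations used Python 3.11.15 with pandas 2.3.3, NumPy 2.4.6 and SciPy 1.17.1, and figures used Matplotlib 3.10.9.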

Results

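Sites of N6-methyladenosine (m6A), a methyl mark carried by adenosines inside messenger RNA, were mapped in bone marrow-derived macrophages of 2 wild-type mice. All cultures had been exposed for 3 h to lipopolysaccharide (LPS), a component of the bacterial outer membrane that activates macrophages through Toll-like receptor 4, so no comparison with resting cells was possible. The assay, m6A-eCLIP, sequences the RNA fragments bound by an antibody against m6A and places each site from the positions where reads start. Each mouse gave 1 immunoprecipitated (IP) library and 1 input library of the same RNA, 4 libraries in all. The deposited table of mouse 1 held 45668 called sites and that of mouse 2 held 47747, each site being 1 nucleotide on 1 strand of the mm10 assembly. The score and the fold of read starts (IP over input) of each site are the authors' own values. The depth of each library is unknown here, because the tables give no read numbers, and no interval for a single site could be formed. Intervals on shares of sites below are exact (Clopper-Pearson) 95% intervals that cover counting error only, and neither sites nor genes are independent replicates.

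The first question was how many sites were enriched by the antibody in each animal. A site was called enriched where the fold of IP over input was at least 8, a log2 fold of 3. In mouse 1, 37333 sites in 7721 genes were enriched, which was 81.7% of its called sites (81.4% to 82.1%). In mouse 2, 37764 sites in 7601 genes were enriched, 79.1% of its called sites (78.7% to 79.5%). The median fold of the enriched sites was 18.1 in mouse 1 and 18.3 in mouse 2. None of the 11 mitochondrial sites of mouse 1 or of the 10 of mouse 2 was enriched. The folds are mostly a ratio of whole numbers with a denominator of at most 20, times a constant that differed between the tables. In 62.1% of the sites of mouse 1 and 62.0% of those of mouse 2 that ratio was a whole number. Read numbers were not given, so an order by fold that follows read starts in the IP, and with them transcript abundance, is not ruled out. The higher share in mouse 1 turned to a higher share in mouse 2 (81.7% against 82.3%) when the limit of 8 was set before the constant.

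The 10 genes with the highest mean fold over both animals included Trim25, Helz2, Jun, Jund and Csf1, and 8 of the 10 sites lay in 3' UTRs. The strongest was in the 3' UTR of Trim25, a ubiquitin ligase of RIG-I signalling, on chromosome 11 at position 89016745, with a fold of 574 in mouse 1 and 1362 in mouse 2. A site in the coding sequence of Helz2, an interferon-induced helicase, on chromosome 2 at 181235069, had folds of 572 and 639. Sites in the 3' UTRs of Jun (chromosome 4 at 95049993) and Jund (chromosome 8 at 70700136), subunits of AP-1, had folds of 443 and 528, and of 393 and 421. The macrophage growth factor Csf1 carried a 3' UTR site on chromosome 3 at 107742977 with folds of 547 and 305. The kinase Csk, which restrains Src-family kinases, and the myeloid lectin receptor Clec5a carried 3' UTR sites with folds of 383 and 420, and of 332 and 359. Cenpb (831 and 318) and Plec (516 and 454) were also among the 10. By number of shared enriched sites the leading genes were Ahnak with 93, Plec with 73, Rnf213 and Helz2 with 63 each and Son with 46. Ahnak, Plec and Rnf213 encode very large proteins.

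Whether the same nucleotides were enriched in both animals was asked next. Of the enriched sites of mouse 1, 29288 (78.5%, 78.0% to 78.9%) were enriched at the same nucleotide and strand in mouse 2, and these made up 77.6% (77.1% to 78.0%) of the enriched sites of mouse 2. Among the 38082 sites called in both tables, 3023 were enriched in mouse 1 only, 2730 in mouse 2 only and 3041 in neither, which gave an odds ratio of 10.8 (Fisher's exact test, two-sided, with a p too small for double precision). The shared sites fell in 6798 genes, 86.9% of the 7827 genes with a called site in both animals, and 1910 of these genes had exactly 1 such site while 630 had at least 10. Sharing followed the score: when the sites of mouse 1 were ordered by score into 5 equal groups, 50.1% of the lowest group were called in mouse 2, against 99.9% of the highest. For mouse 2 these shares were 43.5% and 99.4%.

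Across sites enriched in both animals, the log2 folds had a Pearson r of 0.66 and a Spearman rho of 0.63, and across all sites called in both the values were 0.74 and 0.70. The median absolute difference between the animals was 0.49 on the log2 scale for the sites enriched in both. Sites, not animals, are the points of these correlations, which carry no p-value for that reason. An order by fold that follows transcript abundance is not ruled out, so the correlations cannot separate agreement in methylation from agreement in abundance. The stricter limit of log2 fold 4 lowered the count of enriched sites by more than 1.5 times, to 21661 in mouse 1 and 22107 in mouse 2.

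**Figure D1:**
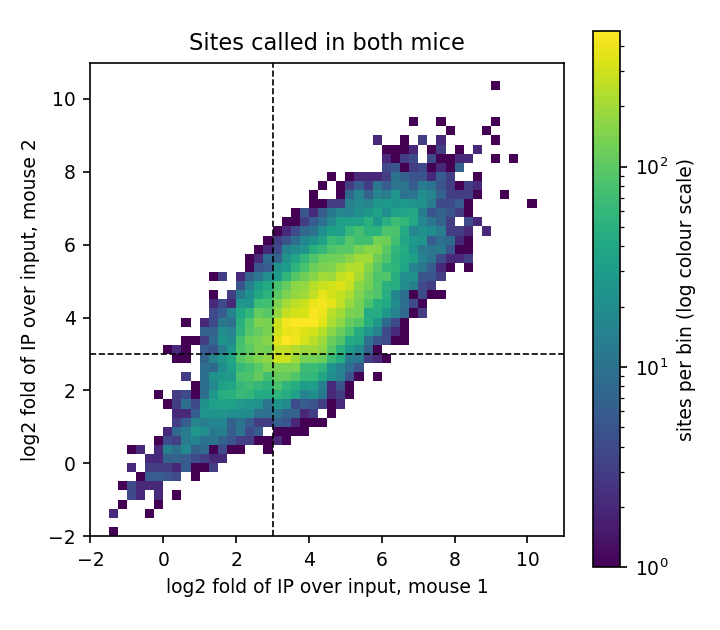
Log2 fold of IP over input in mouse 1 (x axis) against mouse 2 (y axis) for the 38082 sites called in both animals, as the number of sites per bin on a log colour scale. Dashed lines mark the limit of log2 fold 3, and the 29288 sites above both lines were enriched in both.

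Enriched sites lay mostly in coding sequence and 3' UTRs, and sites in 5' UTRs and at 3' splice sites were enriched less often than sites elsewhere. Coding sequence held 41.8% of the enriched sites of mouse 1 (41.3% to 42.3%) against 26.2% of its other called sites, an odds ratio of 2.02. In mouse 2 the shares were 41.7% (41.2% to 42.2%) and 28.4%, an odds ratio of 1.80. The 3' UTR held 35.6% (35.1% to 36.1%) of the enriched sites of mouse 1 and 36.6% (36.1% to 37.1%) of those of mouse 2, with odds ratios of 1.93 and 1.92. The 5' UTR held 15.0% (14.7% to 15.4%) of the enriched sites and 36.7% of the other called sites of mouse 1, an odds ratio of 0.30. In mouse 2 it held 14.6% (14.2% to 15.0%) and 34.0%, an odds ratio of 0.33. The median fold of 5' UTR sites was 10.03 in mouse 1 and 10.1 in mouse 2, while that of 3' UTR sites was 17.4 and 17.3. Of the sites at 3' splice sites, the ends of introns, only 54 of 232 were enriched in mouse 1 and 41 of 251 in mouse 2, with odds ratios of 0.066 and 0.051 and median folds of 2.40 and 2.25.

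These differences were tested with Fisher's exact test (two-sided) for 15 annotated positions in each mouse and adjusted by the Benjamini-Hochberg method over the 30 tests. The adjusted p was 3.3e-159 and 8.4e-133 for coding sequence in mouse 1 and mouse 2, 8.8e-127 and 7.8e-148 for the 3' UTR, 1.8e-83 and 2.6e-100 for 3' splice sites, and too small for double precision for the 5' UTR. Intergenic sites were also enriched less often in both mice, at 68.5% of 1445 and 62.2% of 1534 sites, with adjusted p of 1.7e-34 and 5.6e-53. The same held for distal introns (odds ratios 0.65 and 0.63), proximal introns (0.57 and 0.57) and noncoding exons (0.71 and 0.77). Each position was set against all other sites together, so the odds ratios of the positions depend on each other. Sites of 1 transcript are not independent, which makes these p-values too small. With only the strongest site of each gene counted, all odds ratios named here for the 5' UTR, coding sequence, 3' UTR and 3' splice sites kept their direction.

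**Figure D2:**
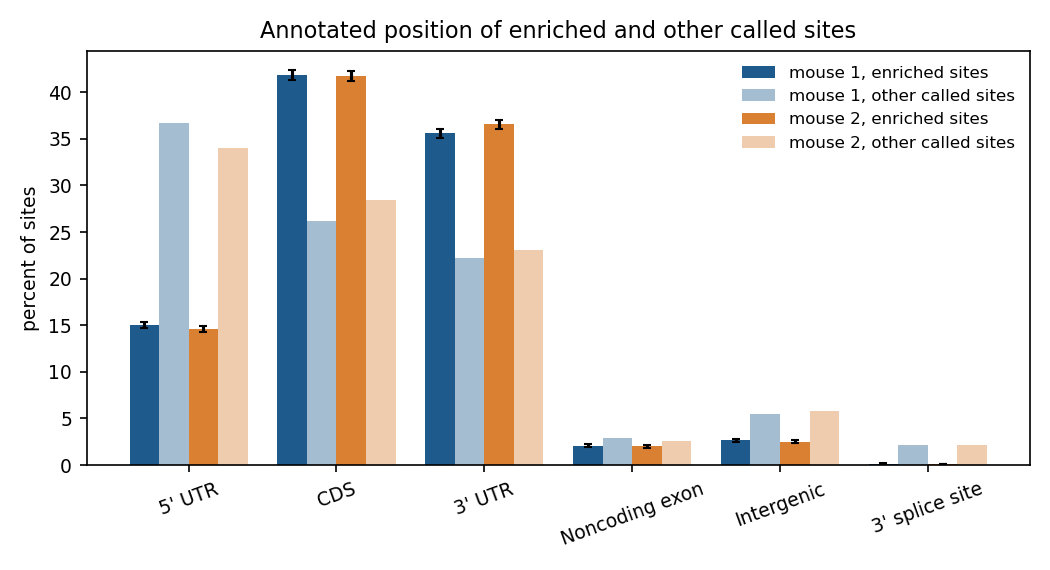
Percent of enriched sites (dark bars, with exact 95% intervals) and of other called sites (light bars) in 6 annotated positions, for mouse 1 (blue) and mouse 2 (orange). In both animals the 5' UTR bar is higher among other called sites (36.7% and 34.0%) than among enriched sites (15.0% and 14.6%), and the coding sequence and 3' UTR bars are the reverse.

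Gene lists served to describe which parts of the macrophage programme carried enriched sites. The 15 lists, fixed before the data were examined, were set against the 7827 genes with a called site in both animals. The cytokine and chemokine list, which also holds the enzyme genes Ptgs2 and Nos2, had 32 genes with a called site in both animals. Of these, 31 carried a shared enriched site, Cxcl9 being the exception with 3 called sites in each mouse and none enriched. The highest folds among them after Csf1 belonged to Pdgfb, whose strongest shared site lay in the 5' UTR (173 and 199), to the costimulatory ligand gene Tnfsf9 (85.9 and 219) and to the 3' UTR of Il1b, which encodes interleukin 1 beta (94.4 and 105). Tnf carried 9 shared enriched sites, Il1rn 8 and Il6 2. Other members rested on 1 shared enriched site in the 5' UTR, at folds near the limit in Il12b (9.44 and 8.74) and Ccl4 (9.16 and 9.86). Of the 122 shared enriched sites of this list, 30 (24.6%) lay in 5' UTRs, against 13.6% over all shared enriched sites, which was not tested. At log2 fold 4, 20 of the 32 genes carried a shared enriched site. No site was called in either mouse for 8 members, among them Ccl5 and Cxcl10, and such genes were left out of the test. The share of 96.9% against 86.8% of other genes did not pass the test (Fisher's exact test, adjusted p = 0.43), and the count lay at the 98.8th percentile of 10000 random lists matched on the number of called sites (78.9th at log2 fold 4).

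Among 37 genes of the NF-kB family and of feedback inhibition of Toll-like receptor signalling, 35 carried a shared enriched site (exact test, adjusted p = 0.53). The phosphatase gene Dusp1 had the highest mean log2 fold (190 and 246), followed by Otulin (181 and 193), Dusp16 (169 and 187) and Tnfaip3 (221 and 110). Otulin and Tnfaip3 encode deubiquitinases that restrain NF-kB and had their strongest shared sites in the 3' UTR, and Tnfaip3 carried 26 shared enriched sites. Of 33 genes of the Toll-like receptor pathway, 31 carried a shared enriched site (exact test, adjusted p = 0.57). That count lay at the 25.3rd percentile of random lists matched on the number of called sites (4.1st at log2 fold 4). Among the receptors with their strongest site in coding sequence, Cd180 carried 29 shared enriched sites with a highest fold of 266 and 256, Tlr2 carried 28 (196 and 165) and Tlr7 carried 27 (287 and 165), while the strongest site of Tlr4, the LPS receptor, lay in the 3' UTR (129 and 126). Over the whole list, 231 of 333 shared enriched sites (69.4%) lay in coding sequence, against 42.4% over all shared enriched sites, a difference that was not tested.

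Interferon-stimulated genes carried a shared enriched site in 55 of 56 cases, or 98.2% against 86.8% of other genes (exact test, p = 0.0081, adjusted p = 0.055), and the single gene without one was Ifi44. After Trim25 the highest folds were in Dhx58 (203 and 467) and Xaf1 (191 and 306), both in coding sequence, and in the 3' UTR of Parp14 (127 and 630). All 35 immediate-early and inducible transcription factors with a called site carried one (exact test, p = 0.011, adjusted p = 0.055), with Etv3 (659 and 164) and Klf6 (209 and 453) next to Jun and Jund. Of 42 macrophage identity genes 40 did (exact test, adjusted p = 0.49), led by Spi1, which encodes the lineage factor PU.1 (155 and 161), Maf (131 and 177), Tfec (76.7 and 184) and Fcgr2b (90.0 and 145), while the cathepsin gene Ctsb had called sites and none enriched. These calls depended on the limit: at log2 fold 4, interferon-stimulated genes (54 of 56, exact test, adjusted p = 5.7e-09), immediate-early genes (31 of 35, exact test, adjusted p = 0.0028) and macrophage identity genes (35 of 42, exact test, adjusted p = 0.011) passed the threshold. Against 10000 random lists matched on the number of called sites, their counts lay at the 71.4th, 92.5th and 79.2nd percentile at log2 fold 3 and, in a ranking added after seeing the data, at the 99.95th, 77.4th and 92.6th at log2 fold 4.

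Of 24 genes of the m6A machinery with a called site in both animals, 21 carried a shared enriched site, 87.5% against 86.9% of other genes (exact test, adjusted p = 1). No site was called under 7 of the 35 symbols of the list, among them 1110037F02Rik and Hnrnpg, other names of Virma and Rbmx, which had called sites. The reader Ythdf1 carried 15 (strongest 142 and 175, coding sequence), Ythdf2 carried 16, and the writer subunits Wtap and Virma carried 13 and 9. Prrc2a (78.2 and 72.2) and the cap methyltransferase Pcif1 (80.2 and 61.6) followed, and the strongest site of Rbm15b was annotated as intronic (79.2 and 75.1). Elavl1 and Mettl5 had called sites and none enriched. The catalytic subunit Mettl3 had 1 called site in mouse 1 and none in mouse 2. Of 49 chromatin regulators 44 carried a shared enriched site (exact test, adjusted p = 1), at the 13.2nd percentile of the matched random lists (3.8th at log2 fold 4). Chd7 (155 and 158) and Setd5 (98.3 and 107) were highest, then Arid1b (83.2 and 91.5) and Crebbp (88.2 and 78.0). In that list 71.9% of the shared enriched sites lay in coding sequence. All 7 long noncoding RNAs with called sites, among them Malat1 with 7 and Neat1 with 9 shared enriched sites, carried one (exact test, adjusted p = 1).

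Cytosolic ribosomal protein genes formed the only list past the threshold at log2 fold 3. Of 28 with a called site in both animals 18 carried a shared enriched site, 64.3% against 86.9% of other genes (odds ratio 0.27, exact test, p = 0.0021, adjusted p = 0.031), and the count lay at the 2.9th percentile of 10000 random lists matched on the number of called sites (9.7th at log2 fold 4). Members were matched by symbol, so the list also holds paralogues such as Rps27l, Rpl7l1 and Rpl22l1, and no gene without a called site is in it. Rpl26, with 3 called sites in each mouse, had none enriched, while Rps27l (65.5 and 68.2), Rpl36 (34.1 and 48.1), Rpl27 (21.7 and 40.4) and Rpl7l1 (24.4 and 38.5) had the highest folds. At log2 fold 1 this call ended (exact test, adjusted p = 1). The respiratory chain list was also matched by symbol, so it holds subunits of ATP synthase, such as Atp5o, Atp5mpl and Atp5c1. Of its 60 genes with a called site in both animals, 49 carried a shared enriched site (exact test, adjusted p = 0.53). This count lay at the 53.1st percentile of the matched random lists (96.2nd at log2 fold 4). They were led by Cox7a2l (91.6 and 75.7) and Ndufb8 (27.0 and 102), then Atp5o (53.7 and 51.03) and Uqcrh (67.2 and 35.6). Atp5mpl and Atp5c1 had called sites and none enriched. The position of the sites set both lists apart from all shared enriched sites, of which 13.6% lay in 5' UTRs: the share was 71.0% (22 of 31) in ribosomal protein genes and 84.8% (78 of 92) in respiratory chain genes.

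**Figure D3:**
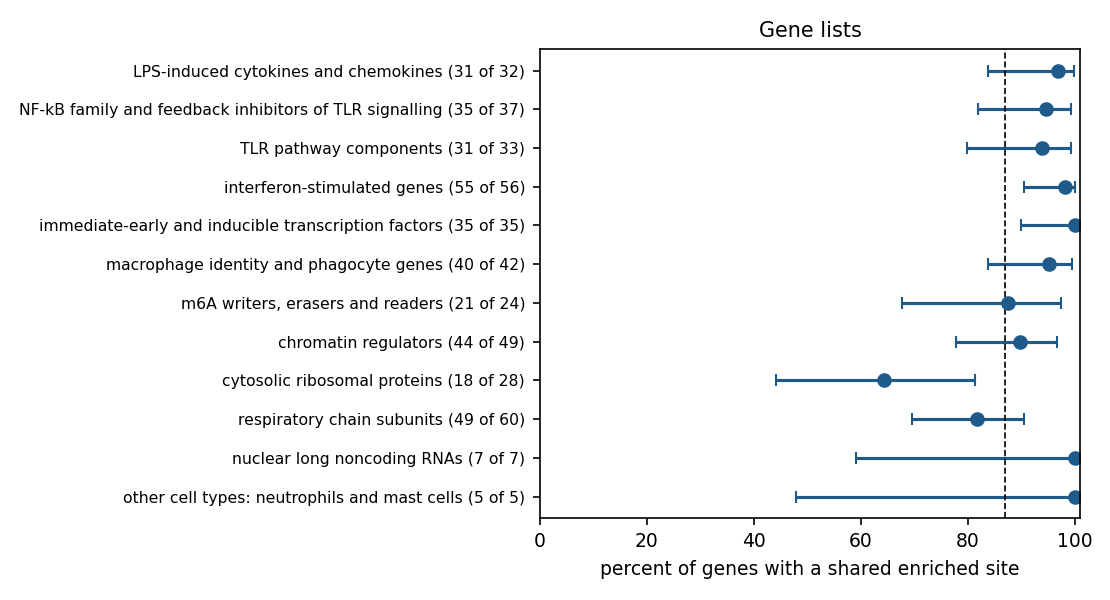
Percent of genes with a shared enriched site (points, with exact 95% intervals) for the 12 lists with at least 5 genes called in both animals. The counts stand beside the names, the dashed line marks the 86.9% over all 7827 genes, and only the interval of cytosolic ribosomal proteins lies wholly below that line.

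Marker genes of other cell types were mostly without called sites. No site was called for 13 of 15 lymphocyte markers, 8 of 15 markers of neutrophils and mast cells, 6 of 10 of dendritic cells and 14 of 15 of stromal, endothelial and erythroid cells. Markers with shared enriched sites were Lck (38.6 and 79.9) and Cd79b (12.03 and 8.67) of lymphocytes and Kdr (44.1 and 52.0) of endothelium. Of the dendritic cell list, Cd83 (190 and 251), Batf3 (28.4 and 55.8) and Irf4 (24.1 and 27.0) carried them. The neutrophil genes Ngp (41.8 and 33.5), S100a9 (19.0 and 30.1), Camp (24.1 and 21.2), S100a8 (16.01 and 20.9) and Ltf together carried 7 shared enriched sites, all in 5' UTRs. None of these lists passed the test against other genes (exact test, adjusted p = 1 for each, with at most 5 members tested).

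Called sites in a single animal were found for 448 genes in mouse 1 and 525 in mouse 2. With at least 3 enriched sites in 1 mouse and none in the other, 20 genes were counted for mouse 1 and 15 for mouse 2. No test exists for these counts with 1 IP library per animal. Genes counted this way could still have called sites in the other mouse that missed the fold limit. Mouse 1 was led by Cav1, which encodes caveolin 1, with 5 enriched sites, and by Pask and Thap4 with 4 each. Cav1 and Thap4 each had 1 called site in mouse 2, and Pask had 0. In mouse 2, Arsa carried 6 and Brip1 carried 5, while mouse 1 had 5 and 1 called sites in these genes and none enriched. Far beyond these, Acod1, the LPS-induced gene of the enzyme that makes itaconate, held 42 called sites in mouse 2, of which 21 were enriched, and no called site in mouse 1. The sites of Acod1 lay on chromosome 14 (gene from 103047012 to 103056573), 23 in the 3' UTR, 16 in coding sequence, 2 in the 5' UTR and 1 in an intron. Their median fold was 8.03 and the highest 173. Their median score was 91.6, against 31.9 over all called sites of mouse 2. Of the 63 sites with a score over 60 that were called in mouse 2 only, 32 lay in Acod1, while 14 such sites were called in mouse 1 only. With 8 further sites downstream of the gene, the sites of Acod1 formed a run of 50 consecutive sites that mouse 2 had and mouse 1 lacked. The next longest run of sites in 1 animal alone held 7. On the opposite strand within 10000 bases of the run, 8 sites were called in each mouse. Acod1 remained specific to mouse 2 under the 6 alternatives run for it, but none of these could add a site to mouse 1, so this is no support. The counts of genes enriched in 1 animal alone did not hold: requiring 5 enriched sites left 1 gene in mouse 1 and 3 in mouse 2. A score of at least 20 gave 10 and 23. At log2 fold 1 they were 17 and 38.

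**Figure D4:**
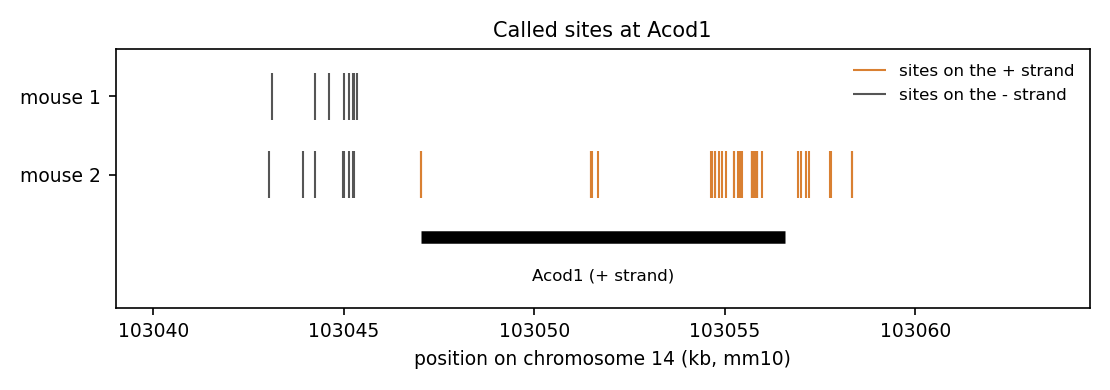
Called sites (vertical ticks) of mouse 1 and mouse 2 around Acod1 on chromosome 14 of mm10, with positions in kilobases on the x axis, sites of the + strand in orange, sites of the opposite strand in grey and the gene as a black bar. Mouse 2 has 42 sites within Acod1 and 8 downstream of it, and mouse 1 has none there, while sites of the opposite strand appear in both.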

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

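The alternatives for the score, the constant of each table and the merging of sites were chosen after seeing the data. No paired analysis was possible because the tables give 1 fold of IP over input per mouse and no values per library. Limits on −log10 p could not be run without a p, regions of at least 20 bases left no site, and models of read counts and the motif search were not run. An overlap rule based on a share of both sites moved nothing for sites of 1 base, and with every deposited site kept the odds ratios between enriched and other sites had no value. Depth could not be varied, since no read numbers were given. The odds ratio of being enriched in both mice (9.09 to 809 over the alternatives) and the odds ratios of the 5' UTR, coding sequence, 3' UTR and 3' splice site kept their direction and stayed past the threshold of the exact test in each alternative that gave a value. Genes with a shared enriched site ranged from 4714 to 7608 over the alternatives that used both mice, and enriched sites of mouse 2 without mouse 1 lay in 7601 genes and those of mouse 1 without mouse 2 in 7721. Leaving out a mouse gave 14.6% to 15.0% for the 5' UTR, 41.7% to 41.8% for coding sequence and 35.6% to 36.6% for the 3' UTR, and these values, like the folds of named sites, cannot leave the spread of 2 animals by construction. Of 413 values under an alternative, 336 stayed within the limits set for their kind.

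The values that moved are grouped here by alternative, as the share of enriched sites of mouse 1 and of mouse 2 that were shared, Pearson r and Spearman rho, and the mean share over the mice of the 5' UTR, coding sequence and 3' UTR. The cause was not tested, except for what follows by construction. A looser or stricter limit keeps more or fewer sites, and a stricter one narrows the range of folds over which the correlations were taken. The rule of 50 bases cannot lower the shares of shared sites. At log2 fold 4 they were 74.3% and 72.8%, 0.58 and 0.53, and 11.7%, 43.4% and 39.0%, with 21661 and 22107 enriched sites and 4 gene lists past an adjusted p of 0.05 in place of 1. At log2 fold 1 they were 83.3% and 79.8%, 0.72 and 0.69, and 18.7%, 39.2% and 33.8%, with 0 lists past the threshold. With every deposited site they were 83.4% and 79.8%, 0.74 and 0.70, and 18.8%, 38.96% and 33.5%, with 0 lists. Sites within 50 bases gave 86.2% and 86.4%, with 0.65 and 0.61. A score of at least 20 gave 83.4% and 79.5%, 0.63 and 0.59, and 15.3% and 41.2% for the 5' UTR and coding sequence. The limit set before the constant gave 79.9% and 75.9% shared and 41.7% in coding sequence. Merging sites within 5 bases gave 79.2% and 78.3% shared, 13.95% in the 5' UTR and 42.3% in coding sequence. With 1 site per gene the 5' UTR, coding sequence and 3' UTR held 21.3%, 34.4% and 38.5%. Genes marked only in mouse 2 numbered 38 at log2 fold 1 and with every site, and 23 with a score of at least 20 and with the limit set before the constant. Genes marked only in mouse 1 numbered 10 at that score. With at least 5 sites required the counts were 1 in mouse 1 and 3 in mouse 2.

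Odds ratios of the 12 gene lists with at least 5 genes called in both mice, with 0.5 added to each cell, crossed 1 in 20 cases, none of them past the threshold after adjustment. For the m6A machinery they were 1.69 at log2 fold 1, 1.54 at log2 fold 4, 1.42 with every site and 4.32 at a score of 20, and for chromatin regulators 0.65 at log2 fold 1, 0.55 with every site and 0.72 among genes with at least 3 called sites. The ribosomal list, called in the main setting, had 1.65 with every site (exact test, adjusted p = 1). Respiratory chain subunits had 1.15 with every site and 1.08 at a score of 20, Toll-like receptor genes 0.84 at that score, and cytokines 0.34 and NF-kB genes 0.58 among genes with at least 3 called sites. Long noncoding RNAs had 0.51 at log2 fold 1, 0.43 with every site and 0.35 among genes with at least 3 called sites, and neutrophil and mast cell markers 0.38, 0.32 and 0.13 in these settings and 0.16 to 1.09 with 1 mouse left out. Of the 3 smaller lists, that of dendritic cells (1.06) fell below 1 in 8 settings, down to 0.19, and that of stromal, endothelial and erythroid cells (0.45) rose to 1.98 at log2 fold 4. A list in which every gene carries a site can fall below 1 through the added 0.5.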

Other observations

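The comparison of gene families and the tests of the Acod1 sites on other LPS genes and on the run itself, of the fold of 5' UTR sites and of their distance to the gene start were chosen only after the results were seen. Among 83 families of genes that share a symbol stem and have at least 10 members with called sites in both mice, the number of shared enriched sites per gene was compared with 10000 random sets of genes of the same size (two-sided permutation test, Benjamini-Hochberg over the families). Solute carriers (Slc, 135 genes, median 4 sites, permutation test, adjusted p = 0.0498) and genes whose symbols begin with Pik (11 genes, median 5 sites, adjusted p = 0.0498) had more sites than random sets, where the median gene of all 7827 had 2. Genes with the stem Rpl, most of them large ribosomal subunit proteins (22 genes, median 1 site, permutation test, adjusted p = 0.033) had fewer. The stem Rps (17 genes, permutation test, adjusted p = 0.55) did not pass the test, but it mixes small subunit proteins with other genes, among them the S6 kinases, and says nothing of that subunit. The sets were not matched on transcript length or abundance. The medians only describe the families and were not what was tested: Rnf and Vps, both with a median of 2, lay on opposite sides of the random sets. The results for Slc and Pik lay just under the threshold and rest on 10000 random draws, so other draws could move them past it. Among lists fixed beforehand the median was 7 sites per gene for Toll-like receptor pathway and interferon-stimulated genes, 6 for chromatin regulators, NF-kB and immediate-early genes, 2.5 for the m6A machinery, 2 for cytokines and 1 for respiratory chain and ribosomal protein genes, and these lists were not tested against each other.

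The absence of Acod1 sites from mouse 1 was set against 3 explanations. A weaker LPS response in mouse 1 could not be judged, since the number of called sites of a gene does not measure its expression. As a set, the other LPS genes kept their sites in mouse 1, unlike Acod1. Over 88 cytokine and interferon-stimulated genes the median log2 ratio of called sites, mouse 1 over mouse 2, was 0. The lower quartile was -0.23 and the upper quartile was 0. These genes held 831 called sites in mouse 1 and 883 in mouse 2. Site calling that leaves out the densest regions of mouse 1 could not be judged: no window outside Acod1 was as dense as the densest inside it, as the test set beforehand required, and the value given instead was chosen after that was seen. The densest window of 150 bases outside Acod1 held 10 sites of mouse 2 and the densest inside it held 22. A difference of the Acod1 locus or its transcription between the animals remains open and cannot be told apart from a loss of that region in processing: the 0 sites of mouse 1 on that strand within the run restate the pattern and test neither. The labels call both mice wild-type and give no difference between them, so no biological explanation named by the design could be tested.

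The 5' UTR position of sites in ribosomal protein and respiratory chain genes held in both mice, at 77.1% of 245 sites in mouse 1 and 76.3% of 262 in mouse 2, against 19.2% and 18.9% in other genes. The length of the genes was argued against as the whole reason, since both shares lay at percentile 100 of 10000 random sets matched on gene length, the highest of which reached 43.7% and 41.2%, but gene length includes introns. Only 22.1% of these genes in mouse 1 and 27.9% in mouse 2 had any site in coding sequence or the 3' UTR, against 83.5% and 83.9% of other genes, so a lack of other sites is part of the pattern. A 5' UTR site was also more frequent, in 86.0% of these genes in each mouse against 51.8% and 52.1% of other genes. Only genes with a called site were counted, which raises that share where other sites are lacking. Short transcripts as the reason stay open because transcript length was not matched. Read starts at transcript 5' ends that are as frequent in the input could not be judged: the median fold of these 5' UTR sites was 10.1 in mouse 1 and 11.5 in mouse 2, but 98.9% and 98.7% of all called sites had a fold of at least 2, so the calling all but fixed that outcome. A modified adenosine next to the cap, which the antibody may also bind, was left open, here and for 5' UTR sites of other genes. Of the 5' UTR sites of both lists, 32.3% in mouse 1 and 32.0% in mouse 2 lay within 20 bases of the gene start, and 78.3% and 77.0% within 100 bases. Over all 5' UTR sites placed against a RefSeq gene start, 16.9% in each mouse lay within 20 bases, and 56.0% and 55.8% within 100. High abundance of the transcripts of both lists was not tested, since no expression values were given.

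The larger share of enriched sites in mouse 1 is consistent with the constant of each table acting on a fixed fold limit. As deposited, the share was 2.66 percentage points higher in mouse 1, and with the limit set on the ratio before that constant the difference was -0.54 percentage points, slightly in favour of mouse 2. The test, set beforehand, asked for a difference under 0.5 percentage points and did not say how a turned sign counts. The first script took the size of the difference without its sign, by which -0.54 just misses that limit and the test decides nothing; that a turned sign meets the limit was decided only after the value was seen. No biological explanation was tested for this difference.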
